A study of Homo sapiens with 6 samples.

How the data were processed

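RNA of 3 human glioblastoma cell lines (A172, T98G and U87MG) was measured on 6 Affymetrix Human Gene 1.0 ST arrays, an oligonucleotide array whose probe sets cover the exons of each gene. Each line gave 1 array after transfection with a negative control oligonucleotide and 1 array after transfection with a precursor of miR-338-5p (called the mimic here), harvested 24 hours after transfection per the labels.

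The authors deposited 1 table of log2 expression values, with 33297 probe sets for each array. Per the submitters' processing notes, the values came from RMA (background correction, quantile normalization and probe summarization) with the package oligo in R 3.0.1; filters and the handling of batches are not given in the sources used here. The scanner files were not used here. The deposited log2 values were taken as they stood, with no further normalization. Array medians lay between 5.06 and 5.14. Arrays of the same line correlated with r from 0.992 to 0.993 over probe sets, and arrays of different lines with r from 0.954 to 0.962. The number of arrays limits the precision: there are 3 arrays per group, and the moderated test has 2 residual degrees of freedom, raised to 6.56 by the variance prior. Quantile normalization in RMA forces the probe values of the arrays to 1 common distribution before they are summarized. A change of most genes in 1 direction would therefore be largely removed from these values. The summarized probe set values still differed somewhat between arrays, as the medians above show.

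Genes were named through the array's platform annotation, which gave 1 symbol for 19460 probe sets and several for 1754, and listed none for 12083. The gene identifier of 19429 of the 1-symbol probe sets matched the RefSeq gene table of GRCh38.p14, used for names only, and 31 kept the annotation's symbol. Probe sets with several or no symbols were left out of the gene tests, as were 24 probe sets for genes on the Y chromosome and for XIST and TSIX. Where a gene had more than 1 probe set (768 of 18394 genes), the brightest by mean over the 6 arrays was used. Genes in the lowest 25% by mean were then left out, which set a minimum mean of 4.28 (log2) and left 13795 genes. Of the entries in the fixed gene lists, 61 were not named by a 1-symbol probe set and 45 lay below the filter; neither kind was analysed here.

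The mimic was compared with the control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) with the cell line as an additive block. The labels give the line of each array, so the lines pair the arrays. As a check, deviations from the group means correlated between the 2 arrays of a line with r = 0.957 in A172, 0.951 in T98G and 0.958 in U87MG, and with no array of another line and the opposite group above r = -0.438. The deviations of a group sum to 0 over its 3 lines, which by itself favours negative values between different lines. Only the values within a line therefore bear on the pairing. Changes are given as mimic minus control on the log2 scale, as the mean over the lines with the SD over the lines (n = 3). The labels give 1 array per line and group and do not say whether it came from 1 culture or a pool. The p-values therefore measure the spread of the response between these lines. With no change at all, a share of about 0.05 of the tested genes would have an unadjusted p under 0.05. Counts at an unadjusted p are to be read against that share. No scan date or batch is given in the labels, so a processing batch that followed the groups could not be separated from the mimic. No untransfected array was analysed here, so effects of the control oligonucleotide itself stay open.

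Gene lists for pathways, cell cycle phases, stress responses, glial identity and other cell types were fixed before the data were examined, as were the main tests, the rule for naming genes and the alternatives, other than those that the closing section says were chosen later. Lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation camera takes its p from the 2 residual degrees of freedom, which makes that form less able to call a list at any correlation. Each list's median was also set against 10000 random lists of the same size, matched on mean expression in 20 bins, and the central 95% of these is called the random range. Agreement between lines was described by correlations across genes and by the number of genes changed by at least 0.5 in the same direction in every line, against the number expected from each line's own counts under independence. Within a line there is no replicate, so differences there carry no test. Lines were compared by limma's F test and pairwise contrasts with the group as an additive term.

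The genes named were the 12 higher and 12 lower genes of largest change among those past the threshold with the same sign in every line; the members of the lists of study-linked targets, miR-338 host gene and line identity; the 4 members of smallest p in each list that was called or moved alike in every line; the 5 highest and 5 lowest genes within each line among genes above the median expression; and the 4 genes of largest contrast for each line. Others are said to have been chosen after their values were seen. Several named genes, among them C1D, TOMM20, RHEB and the ribosomal protein genes, have pseudogene copies in the gene table, and their probe sets may not separate these copies, so these values are uncertain in that respect. A planned comparison of genes with and without a match to the miR-338-5p seed in their 3' UTR was not run, since no 3' UTR sequence was used here.

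The code was tested on 20 simulated data sets with the real arrays' line means, 13795 genes and 200 changed genes each. With spreads drawn from limma's fitted prior, 44.0% of changes of 0.5 (log2), 97.2% of changes of 1 and 99.3% of changes of 1.5 were recovered for the mimic comparison, and 5.4% of the calls were false. With each gene's own moderated spread as the true spread, 9.37% of the mimic calls and 10.6% of the calls between lines were false, above the nominal level. A list shifted by -0.2 was called in 100% of the simulated sets, with 0.05 other lists called on average under drawn spreads. The simulated noise was independent between genes, so both figures hold only for lists whose genes do not vary together. In size this shift also exceeded the medians of most lists called in the real data. Between lines, 99.5% of changes of 2 were recovered under drawn spreads, with 4.94% false calls. Alternatives covered the block, the filter, the choice of probe set, the normalization, the variance prior, the inter-gene correlation, the size limits and each line left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.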

Results

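Gene expression was measured in A172, T98G and U87MG, established cell lines derived from human glioblastoma, an aggressive brain tumour. Each line was transfected with the miR-338-5p mimic or with a negative control, and RNA was taken after 24 hours, which gave 3 arrays per group. The deposited design states that the experiment looked for targets of this microRNA. A microRNA guides silencing complexes to messenger RNAs that carry matching sites, most often in the 3' UTR, and a direct target is then usually lowered. Values are RMA log2 expression. After filtering, 13795 genes were compared.

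The mimic was followed by lower expression of 109 genes and higher expression of 44 genes in limma's paired fit. RAB1A, a small GTPase of transport from the endoplasmic reticulum to the Golgi, fell furthest, by 1.73 ± 0.16 on the log2 scale (SD, n = 3), from a mean level of 10.4 to 8.66. PPP2R5A, a regulatory subunit of protein phosphatase 2A, fell by 1.57 ± 0.11, and SCML1, a Polycomb-related protein, fell by 1.55 ± 0.13. Their adjusted p was 0.00246 in each case. The gene that rose most was MET, the receptor for hepatocyte growth factor, at 1.14 ± 0.15 and adjusted p = 0.00572, or 2.21-fold higher.

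Of the other genes that fell most, MMD changed by -1.53 and GPAT3, an enzyme of triglyceride synthesis, by -1.38 ± 0.60, the widest spread of this group. In A172 with the mimic both stood below the filter level of 4.28, MMD at 3.92 and GPAT3 at 3.99, so the size of their change in that line (-1.33 and -0.72), and with it the mean and spread, is uncertain. ATAD1, a mitochondrial AAA ATPase, changed by -1.43, TMEM64 by -1.34 and SYPL1, a synaptophysin-like membrane protein, by -1.30. DCP2, the enzyme that decaps messenger RNA, changed by -1.29. GNAQ, a G protein alpha subunit, changed by -1.29, and the kinases HIPK3 and PKN2 by -1.22 and -1.20. Adjusted p in these 9 genes lay between 0.00379 for PKN2 and 0.042 for HIPK3. Among lower genes, 18 reached a 2-fold change.

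Genes that rose after MET were PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, at 1.1 ± 0.16, TAPT1 at 1.08 ± 0.14 and WSB1, a substrate receptor of a ubiquitin ligase, at 1.01 ± 0.33. These 4 genes were the only ones past the threshold that were higher by 2-fold or more. CYRIB, which binds RAC1, rose by 0.89, TOMM20, a receptor of mitochondrial protein import, by 0.87 and PIP4K2A, a phosphoinositide kinase, by 0.84. BOD1, a protein of chromosome alignment, rose by 0.79, RAD54L2 by 0.79, PPP2R1B, a scaffold subunit of protein phosphatase 2A, by 0.76, C1D by 0.76 and ZNHIT6, an assembly factor of small nucleolar RNA complexes, by 0.75. Their adjusted p lay between 0.00655 for TAPT1 and 0.0238 for WSB1. The median change was 0.64 over the higher genes and -0.66 over the lower genes, and 0.00675 over all tested genes.

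**Figure D1:**
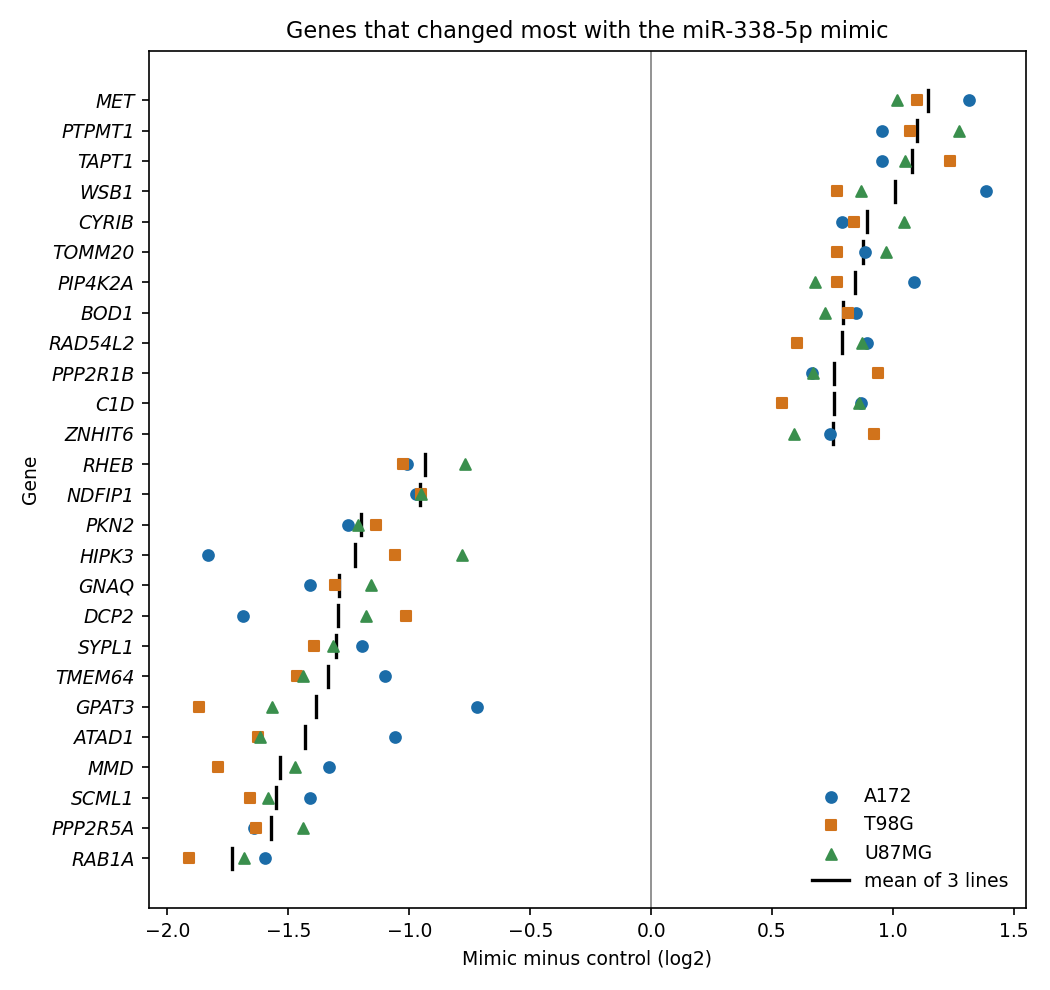
Change with the mimic (mimic minus control, log2, horizontal axis) of the 12 higher and 12 lower genes of largest change and of the 3 study-linked targets, with 1 point per cell line and a bar at the mean of the lines. All points of a gene lie on the same side of 0, which the rule for choosing them requires of all but the targets, from RAB1A at a mean of -1.73 to MET at 1.14.

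The number of genes past the threshold depended on the arrays and on the block: 0 genes passed limma's adjusted threshold without the U87MG arrays (1340 at an unadjusted p under 0.05) and 0 without the cell line in the model (127), against 1634 at an unadjusted p in the full fit, while 61 genes passed without the A172 arrays, 9 of the 44 higher and 42 of the 109 lower genes among them. Without U87MG the changes of the leading genes kept their sign, some larger and some smaller: RAB1A was at -1.75, PPP2R5A at -1.64 and MET at 1.21, while SCML1 was at -1.54, ATAD1 at -1.34 and PTPMT1 at 1.01. A fit without 1 line has fewer residual degrees of freedom than the 2 of the full fit. A lost call therefore does not by itself show that a change rests on the line left out. In the full fit the genes called lower had a median of -0.658 in A172, -0.707 in T98G and -0.673 in U87MG. Those called higher had 0.712, 0.577 and 0.66 in the same order. Calling genes on the mean over the lines favours such likeness. RAD54L2, ZNHIT6 and C1D did not pass without A172 (adjusted p from 0.056 to 0.0738). The number also moved with the gene filter and the variance model, from 60 genes with no filter to 472 with a variance prior that follows expression, and with no filter WSB1, C1D, GPAT3, HIPK3, RFC3 and TGFBR1 did not pass (adjusted p from 0.0518 to 0.0759).

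The 3 genes that the study itself put forward as targets, as far as is known of it, were lower in every line. Besides PPP2R5A, NDFIP1, an adaptor of NEDD4-family ubiquitin ligases, fell by 0.96 ± 0.01 (SD, n = 3; adjusted p = 0.00547 with limma), from 7.87 to 6.91. RHEB, the small GTPase that activates mTOR complex 1, fell by 0.93 ± 0.14 (adjusted p = 0.0111), from 9.88 to 8.95. All 3 passed both over all genes and adjusted over the list alone, but the study may have chosen them on these same arrays, so neither count is independent evidence of their direction. AATK, whose intron hosts the miR-338 hairpin, differed by -0.15 ± 0.12 (adjusted p = 0.518). The hairpin itself was not analysed here.

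Changed genes in the lists of related pathways can be set against 153 changed among all 13795 tested genes. Of 15 measured subunits of protein phosphatase 2A, PPP2R5A fell and PPP2R1B rose, and camera did not call the list (median 0.0193, mean -0.0217, adjusted p = 0.866). Of 15 NEDD4-family ligases and adaptors only NDFIP1 passed over all genes, while ARRDC4 at 0.33 also passed adjusted over the list alone (list median 0.0603, adjusted p = 0.70). Of 36 genes of the mTOR and PI3K pathway only RHEB passed (median -0.0199, adjusted p = 0.40). Among 27 genes of receptor tyrosine kinase and MAPK signalling MET rose, and EGFR, the epidermal growth factor receptor, differed by -0.46 ± 0.12 and passed only adjusted over the list alone (0.0118, against 0.0639 over all genes). That list had a median of -0.014, a mean of 0.0317 and an upward camera direction with adjusted p = 0.926. Of 20 genes of microRNA processing and silencing PAN3, a subunit of a deadenylase, fell by 0.72 ± 0.07 (adjusted p = 0.0151), and TNRC6C at 0.43 and CNOT7 at 0.34 passed adjusted over the list alone (list median 0.0448, adjusted p = 0.204). ARRDC4, PAN3, TNRC6C and CNOT7 were chosen after their values were seen. The mixed form of fry, which allows either direction within a list, called each of these lists. Its adjusted p was 0.000616 for NEDD4-family genes and 0.0283 for receptor tyrosine kinase and MAPK signalling. It was 0.00744 for protein phosphatase 2A, mTOR and PI3K, and microRNA genes. The protein phosphatase 2A, NEDD4-family and mTOR lists each hold a study-linked target, so their calls are not independent evidence.

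Of 27 lists tested with camera, 3 were called upward and 5 downward at the preset correlation, all with small shifts, and 0 were called with an estimated correlation (adjusted p = 0.832 or 0.839 for each of the 8). The latter form rests on 2 residual degrees of freedom, and TGF-beta, whose estimated correlation of -0.0302 lay below the preset 0.01, lost its call too, so the loss is not a measure of the correlation alone. The estimated correlation was above the preset in each of the other called lists. It was 0.737 for interferon response, 0.309 for oxidative phosphorylation, 0.166 for G2/M, 0.143 for ribosomal proteins and 0.137 for hypoxia and glycolysis. Cholesterol biosynthesis had 0.0332 and G1/S 0.0119. The preset and the random ranges make little or no allowance for such correlation, so calls of the lists with high estimates may be overstated. Of 39 measured genes of G2/M and mitosis 30 had a positive change and 0 passed singly; the median was 0.0916 and the adjusted p 0.00247. Its members of smallest p were BUB3 at 0.34, KIF11 at 0.25, CCNB2 at 0.21 and CCNA2 at 0.21. The 38 genes of G1/S and DNA replication had a median of 0.0779 (adjusted p = 0.042), with 31 positive; its one changed gene went the other way, since RFC3, a subunit of the clamp loader of DNA replication, fell by 0.58 (adjusted p = 0.0315, and 0.0692 without A172 or 0.0745 without T98G). GINS3 at 0.46, CDK6 at -0.22 and RFC4 at 0.24 followed and did not pass. Cholesterol biosynthesis had the lowest median of the called lists, -0.121 over 18 genes (adjusted p = 0.000838), of which 16 were negative. None of them passed over all genes, and IDI1 at -0.35 and HMGCS1 at -0.32 passed adjusted over the list alone; STARD4 differed by -0.27 and EBP by -0.16. Of 29 genes of hypoxia and glycolysis 22 were negative (median -0.084, adjusted p = 0.00242); NDRG1 at -0.48 and ADM at -0.58 passed adjusted over the list alone and none over all genes (0.0505 for NDRG1, which passed in 6 of the alternatives, and 0.0936 for ADM), and KDM3A differed by 0.26 and PFKP by -0.40. These 4 lists lay outside their random range in the same direction in A172, T98G and U87MG. With an estimated correlation the adjusted p was 0.832 for each of them.

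In each of the other called lists the median lay inside the random range in at least 1 line. Of 36 genes of oxidative phosphorylation 33 were negative (median -0.0809, adjusted p = 0.000838); NDUFB5 at -0.45 passed adjusted over the list alone, and NDUFB3 at -0.29, NDUFA9 at -0.24 and NDUFA8 at -0.18 did not. Of 38 cytosolic ribosomal protein genes 34 were negative (median -0.0506, adjusted p = 0.0406), led by RPL22 at -0.23, RPS3 at -0.12, RPL10A at -0.12 and RPS14 at -0.12, none of which passed; in U87MG this list had a median of 0.0144. The TGF-beta list had a median of -0.10 over 23 genes (adjusted p = 0.00447). Its receptor gene TGFBR1 fell by 0.70 ± 0.22 (adjusted p = 0.0325, and 0.0673 without A172), ID1 at -0.43 passed adjusted over the list alone, and BHLHE40 at -0.31 and ACTA2 at 0.30 did not pass. The interferon response list had a median of 0.198 over 35 genes (adjusted p = 0.0017), with 0 genes past the threshold; OASL at 0.33, IFIH1 at 0.61, IFI44 at 0.53 and RIGI at 0.49 had the smallest p. Without the A172 arrays its median was -0.0528 (adjusted p = 0.184). With an estimated correlation the adjusted p was 0.832 for oxidative phosphorylation and TGF-beta and 0.839 for the ribosomal and interferon lists, so that 0 of 27 lists were called, and 0 had an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance one way, called 0 lists, and its mixed form, which allows either direction, called 16.

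**Figure D2:**
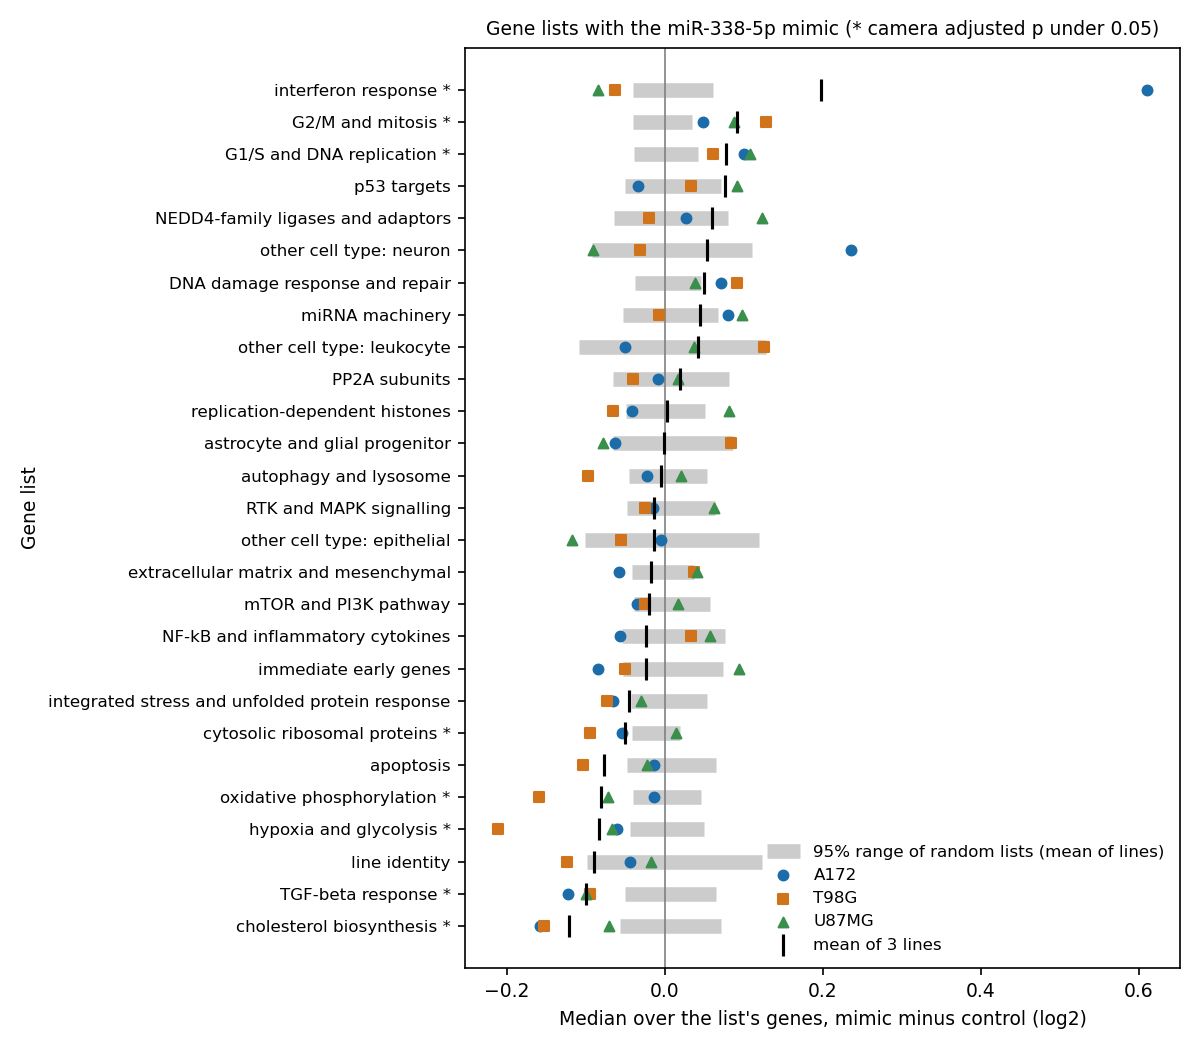
Median change with the mimic (mimic minus control, log2, horizontal axis) of each of the 27 gene lists tested, with 1 coloured point per cell line and a black bar for the change averaged over the lines; the grey bar is the central 95% of random lists of the same size and expression, for the average over the lines. The interferon list stands at 0.61 in A172 and at -0.06 and -0.09 in the other lines, while the points of the other lists lie between -0.21 and 0.24.

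Leaving out a line moved several of these calls. Without T98G the adjusted p was 0.275 for G2/M, 0.21 for hypoxia and glycolysis, 0.144 for oxidative phosphorylation and 0.352 for the ribosomal list, and without A172 the ribosomal list had 0.20; G1/S was not called without any 1 of the lines (lowest adjusted p 0.0663), and cholesterol biosynthesis and TGF-beta were called without each. The TGF-beta median was -0.06 without U87MG, against -0.10 with all lines. The hypoxia and glycolysis median was -0.0468 without T98G and -0.135 without A172, against -0.084, and the ribosomal median -0.0791 without U87MG, against -0.0506. The interferon median was 0.391 without U87MG, against 0.198. The calls of the ribosomal list and of G1/S were also lost with the lower 50% of genes left out (adjusted p = 0.0571 for both) and with arrays centred on their medians (0.0659 for both), and that of the ribosomal list with no filter (0.0531), repeated quantile normalization (0.1455) and loess removal (0.172). Without the cell line in the model G2/M, interferon response and oxidative phosphorylation were called, and the other 5 lists had adjusted p from 0.076 to 0.101.

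Camera did not call the remaining lists, although the medians of 4 of them lay outside their random ranges. DNA damage response and repair, the process that the study concerned as far as is known of it, held 0 changed genes of 45 (median 0.0495, adjusted p = 0.189). Its median lay above the random range of -0.0373 to 0.0459, as it did in A172 (0.0708, upper end 0.0699) and T98G (0.0912, upper end 0.0275) but not in U87MG (0.0387). CLSPN, a mediator of the replication checkpoint, at 0.28 and LIG4, a ligase of end joining, at -0.39 had its smallest p, with adjusted p = 0.186 and 0.234; these genes, and SESN1, MCL1 and LOXL2 in the lists that follow, were chosen after their values were seen. The p53 target list had a median of 0.0762 over 23 genes (upper end of the random range 0.0707, adjusted p = 0.40), with SESN1 at 0.41 past the threshold over the list alone. Apoptosis genes had a median of -0.0771 over 25 (lower end of the random range -0.0477, adjusted p = 0.244), while MCL1, which protects cells from apoptosis, was at 0.50 and passed over the list alone (0.0144, against 0.0506 over all genes). The unfolded protein and integrated stress list had a median of -0.0453 over 30 genes (lower end of the random range -0.0432, adjusted p = 0.204), and the 25 replication-dependent histone genes had 0.00267 (adjusted p = 0.978), with the sign turned when arrays were centred on their medians. The 21 NF-kB and cytokine genes had a median of -0.024 and a mean of 0.0199 with an upward test (adjusted p = 0.863), and the 21 immediate early genes a median of -0.0244 and a mean of 0.00167 with a downward test (adjusted p = 0.866). Extracellular matrix genes had a median of -0.0172 over 36 (adjusted p = 0.908), with LOXL2, a lysyl oxidase, at -0.53 and past the threshold over the list alone. The 27 autophagy and lysosome genes had -0.00545 (adjusted p = 0.665), with the sign turned by repeated quantile normalization.

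Camera did not call the tested lists of markers of identity and of other cell types either. Astrocyte and glial progenitor genes had a median of -0.000988 and a mean of 0.00314 over 14 (adjusted p = 0.926). Leukocyte markers had 0.0419 over 6 genes (adjusted p = 0.747), with the sign turned by repeated quantile normalization, neuronal markers 0.0531 over 9 (adjusted p = 0.908) and epithelial markers -0.0141 with a mean of 0.0105 over 6 (adjusted p = 0.926). In A172 the neuronal median was 0.235, above that line's random range of -0.172 to 0.161, against -0.032 in T98G and -0.091 in U87MG. This difference between lines was not tested. The mixed form of fry called the leukocyte and line identity lists (adjusted p = 0.0445 for both). Only 2 oligodendrocyte and 4 endothelial markers were measured; their medians of -0.0175 and 0.0172 were not tested. Of the 7 measured line identity genes (median -0.0897, adjusted p = 0.182), EGFR passed over the list alone. The others were MGMT, which repairs alkylated DNA, at -0.15, IL13RA2 at -0.12, CDKN2B at -0.09, CDKN2A at -0.01, GFAP at 0.04 and TERT at 0.01. CDKN2A in the U87MG control and IL13RA2 in both T98G arrays stood below the filter level. The sign of TERT turned when arrays were centred on their medians.

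The lines were compared to ask whether they responded alike. Across genes, the change in A172 correlated with that in T98G with Pearson's r = 0.279 and a Spearman coefficient of 0.208, with that in U87MG with 0.293 and 0.212, and T98G with U87MG with 0.272 and 0.163. Genes are not independent replicates, so no p is given, and each line has its own control. A change of at least 0.5 in all 3 lines was seen for 25 higher genes, against 0.0542 expected if the lines were independent, and for 69 lower genes, against 0.0985 expected. The expected numbers treat all genes as equally variable. Genes that vary more pass 0.5 in every line more often, so these numbers may be too low. At a change of at least 1 there were 1 higher and 11 lower genes. Over all tested genes 34.3% had the same sign in every line, where 25% would if signs were independent and equally likely. Trends shared by the arrays of a group could raise that share and were not taken into account.

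Within single lines, where no replicate allows a test, 24 genes were higher and 22 lower by at least 1 in A172, 10 and 30 in T98G, and 14 and 22 in U87MG. The rankings that follow hold only among genes whose mean level lay above the median of the tested genes; dimmer genes, such as MMD at -1.79 in T98G and TAPT1 at 1.24 there, can lie further out. RAB1A and SCML1 were among the 5 lowest such genes of every line, and MET among the 5 highest. GPAT3, ATAD1 and TMEM64 completed the lowest 5 of T98G and U87MG, with GPAT3 at -1.87 and -1.57. In A172 HIPK3 at -1.83, DCP2 at -1.69 and GNAQ at -1.41 stood there instead. The highest 5 of these brighter genes in A172 were IFI44L at 2.53, WSB1 at 1.38, IFI6 at 1.34, MET at 1.32 and IFI44 at 1.27, of which IFI44L, IFI6 and IFI44 are interferon-induced. IFI44L was at 0.20 in T98G and -0.15 in U87MG; its level in the A172 control was 4.01, below the filter level of 4.28, so the size of its difference there is uncertain. In U87MG the cyclin gene CCND3 was at 1.07, against 0.29 in A172 and 0.72 in T98G, and MYH10, a non-muscle myosin, at 1.05, against 0.09 and 0.12. MYH10 stood at 3.46 in the U87MG control, below the filter level of 4.28, against 8.77 in the A172 and 8.17 in the T98G control. PTPMT1, CYRIB and MET made up the highest 5 there, and PPP2R1B and BOD1 joined these genes in T98G.

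**Figure D3:**
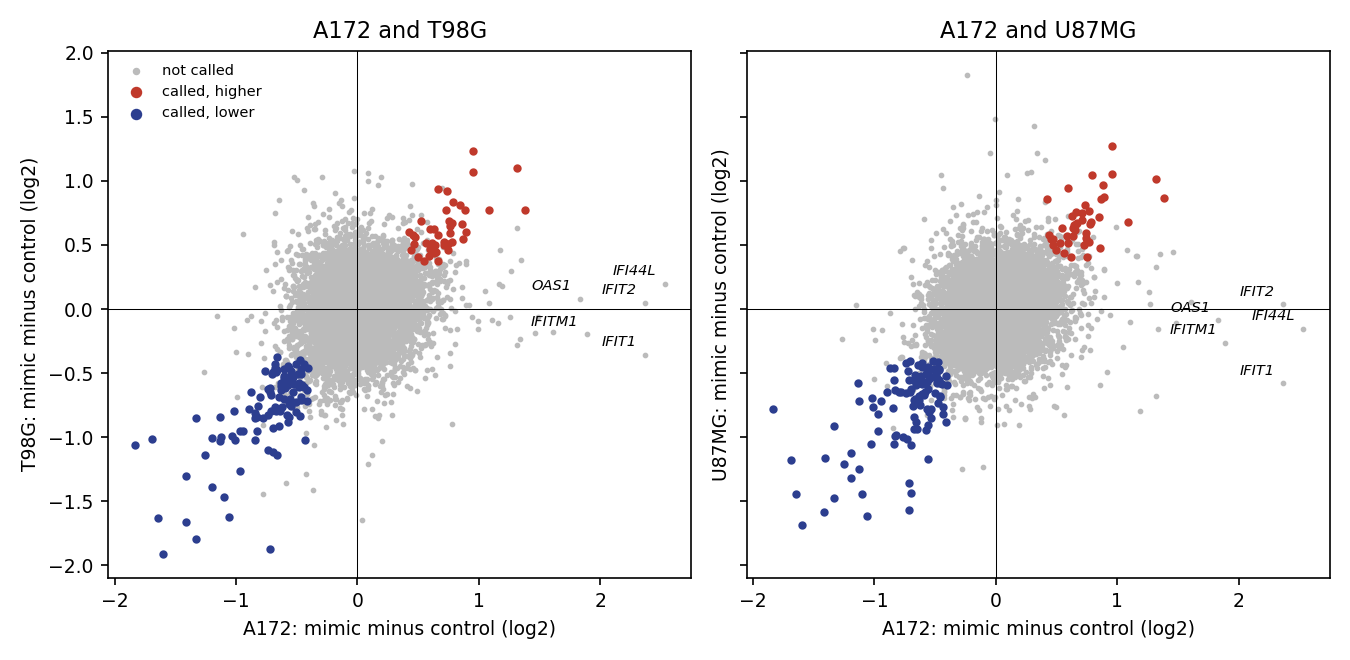
Change with the mimic (mimic minus control, log2) of each of the 13795 tested genes in A172 (horizontal axis) against T98G (left) or U87MG (right); genes called lower are blue, genes called higher red and others grey. The called genes lie in the quadrants of like sign, which calling them on the mean over the lines favours, and the labelled interferon-induced genes, such as IFI44L at 2.53, are high in A172 and near 0 or below in the other lines.

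Many more genes differed between the lines than between mimic and control. Limma's F test called 9309 of 13795 genes between lines, and the pairwise contrasts called 6963 genes between A172 and T98G, 7476 between A172 and U87MG and 6504 between T98G and U87MG. SUCNR1, the succinate receptor, had a mean level of 10.9 in A172 (SD 0.0126, 2 arrays) against 1.98 in T98G and 1.95 in U87MG, and the noncoding RNA UCA1 11.5 against 4.28 and 3.98. A172 was low in AHR, the aryl hydrocarbon receptor, at 2.77 against 10.8 and 9.94, and in KYNU, kynureninase, at 3.26 against 10.2 and 10.0. T98G was high in CDH6, a cadherin, at 10.5 against 3.65 in A172 and 3.62 in U87MG, in GABRA2 at 9.57, IGFBP5 at 10.9 and the aldo-keto reductase AKR1B10 at 11.4. U87MG was high in the protease gene TMPRSS15 at 9.62 against 2.56 in A172 and 2.46 in T98G, in GREM1, a BMP antagonist, at 10.4, PALMD at 9.64 and the aquaporin AQP9 at 9.28. Levels under the filter level of 4.28, such as those of SUCNR1 in T98G and U87MG and of AHR in A172, were not shown to be above background, so the size of such differences is uncertain. All of these genes had an adjusted p of 9.3e-07 or less for their line against the mean of the others, the highest being that of GABRA2.

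Among the line identity genes MGMT was higher in T98G, at 6.08 ± 0.09 (SD, 2 arrays), than in A172 at 5.09 and U87MG at 5.02 (adjusted p = 0.000176, F test). IL13RA2, an interleukin receptor found on many glioblastomas, was at 2.467 in T98G against 7.326 and 7.005 (adjusted p = 8.11e-07). CDKN2B was at 5.72 in T98G against 5.04 and 4.80 (adjusted p = 0.00505), and EGFR at 8.26 in U87MG against 8.63 and 8.78 (adjusted p = 0.00758). GFAP, CDKN2A and TERT did not pass (adjusted p = 0.066, 0.308 and 0.561). These p-values, and those behind the counts between lines above, rest on 2 arrays per line, 1 of them with the mimic. They do not measure how separate cultures of a line vary. A processing batch that followed the lines could not be separated from the differences between lines.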

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

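The tests of swapped labels and of an intensity trend were set out before their results were seen. The differences between lines given here rest on 1 pair of arrays per line and were not tested.

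The interferon response list moved apart between the lines. Its median was 0.611 in A172 and -0.0852 in U87MG, both outside the random range of the line and on opposite sides of 0, and -0.0635 in T98G, inside the range. In A172 23 of 35 members were higher by at least 0.5 and 13 by at least 1, while T98G and U87MG had 0 such genes. The highest were IFI44L at 2.53, IFIT2 and IFIT1 at 2.37, IFITM1 at 1.89 and OAS1 at 1.83, interferon-induced genes of which IFI44L is named by the rule and the others were chosen after their values were seen. In the A172 control IFI44L stood at 4.01, below the filter level of 4.28 and so not shown to be above background, which leaves the size of its difference uncertain, against 6.28 in T98G and 8.78 in U87MG. IFIT2, IFIT1, IFITM1 and OAS1 had mean levels no higher than the median of the tested genes. Their levels in the A172 control are not given here, so the sizes of their differences are uncertain too.

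A swap of the labels of both A172 arrays would have turned the other changes of that line too. The 51 genes called lower from T98G and U87MG alone had a median of -0.777 in A172 (SD 0.427), and 50 of them were negative there, which argues against a swap. With each line's loess trend of difference on mean removed, the A172 median of the list was 0.605, above 0.4, the bound set for this test, which argues against an intensity trend as the cause. A response of A172 to the transfected RNA, a response of its culture dish unrelated to the mimic, or a difference in processing of this 1 pair may each account for the pattern, and with 1 array per group in the line they stay open; no test here bears on which.

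The extracellular matrix and mesenchymal list had a median of -0.0581 in A172 and 0.0373 in T98G, both just outside their random ranges and of opposite sign, and 0.0404 in U87MG.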

How the results depend on the processing

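The loess removal for genes changed and for lists, and the arrays left out singly between lines, were chosen after seeing the data; the other alternatives were fixed before. No named gene past the threshold changed direction under any alternative run. Without the cell line in the model (no replicate block) 0 genes were higher, 0 lower and 0 in all (127 at an unadjusted p under 0.05), and 3 lists were called; here the differences between lines enter the error. With no filter on low means 15 genes were higher and 45 lower (60 in all), with the lower 50% by mean left out 125 and 239 (364), with a variance prior that follows expression 171 and 301 (472), and with arrays centred on their medians 57 and 179 (236), where the median of all genes was -0.00954. The cause of these shifts was not tested. Of the 44 higher and 109 lower genes, 14 and 45 were kept with no filter, 41 and 105 with the lower 50% left out, 43 and 109 with the trended prior, and all 153 with centring, repeated quantile normalization and loess removal (52 higher and 132 lower). The mean of all probe sets and the robust prior stayed within 1.5 times of the counts.

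Leaving out a line gave from 0 to 41 higher genes, 0 to 79 lower and 0 to 120 in all, with 0 each without U87MG (1340 at an unadjusted p) and 10 higher and 51 lower without A172; without U87MG MET was at 1.21 and RAB1A at -1.75, close to their values over all lines, with adjusted p of 0.0885 and 0.0717. List calls ranged from 3 without T98G to 7 without U87MG, and 0 held with an estimated inter-gene correlation, a form of the test limited by 2 residual degrees of freedom. The estimates lay above the preset in all called lists but TGF-beta. The interferon median ranged from -0.0528 without A172 to 0.391 without U87MG. Each fit without a line had fewer residual degrees of freedom than the 2 of the full fit.

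Members of lists that missed the threshold over all genes passed under some settings: NDRG1 in 6 (adjusted p from 0.00133 to 0.0461), ADM in 4, EGFR, NDUFB5 and GINS3 in 3 each, IDI1, HMGCS1 and ID1 in 2 each, and RFC4, BUB3 and BHLHE40 in 1 each. Signs turned only for values that did not pass, other than the interferon list. With a line left out the ranges were -0.148 to 0.248 for CDKN2A, -0.243 to 0.0997 for CDKN2B, -0.00978 to 0.0722 for GFAP and -0.0627 to 0.0999 for TERT, which was -0.00374 with centred arrays. For list medians they were -0.0212 to 0.0257 for histones, -0.0369 to 0.0994 for NF-kB, -0.0163 to 0.0694 for protein phosphatase 2A, -0.0148 to 0.0972 for NEDD4-family genes, -0.0865 to 0.0251 for immediate early genes, -0.0203 to 0.0161 for extracellular matrix, -0.0259 to 0.00929 for astrocyte genes, -0.0587 to 0.000244 for autophagy, -0.00635 to 0.0751 for leukocyte, -0.0418 to 0.0811 for neuronal and -0.0406 to 0.0282 for epithelial markers. With no filter leukocyte markers had -0.0282 and neuronal markers -0.0148; with the lower 50% left out histones had -0.000553 and NF-kB 0.00334; with the mean of probe sets leukocyte markers had -0.00135 and epithelial markers 0.0269; with repeated quantile normalization autophagy had 0.00116 and leukocyte markers -0.0431; with centred arrays histones had -0.0136.

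The mean r of the 3 pairs of lines, 0.281, was 0.196 with no filter and 0.453 with the lower 50% left out. At a size of 1 instead of 0.5, 1 gene was higher and 11 were lower in every line. Genes higher by 1 within a line numbered 13 in A172, 4 in T98G and 8 in U87MG with the lower 50% left out, and in T98G 4 with centred arrays and 5 with loess removal. Between lines the F test called 7573 to 9625 genes under the other settings and 8005 to 8982 with 1 array left out. RMA values carry no detection call here, so signal over background was not judged beyond the filter. The planned seed match comparison and all its alternatives were not run, and camera was not run with the robust prior.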

Other observations

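The genes in this paragraph and the next were chosen after their values were seen, and as no list of their processes was fixed or tested for enrichment they stand as single genes. The small GTPase genes RAB28 at -1.02 ± 0.03 (SD over the lines), RAB18 at -0.56 and RAB22A at -0.55 fell, as did GOLT1B, a Golgi transport protein, at -0.77. RNF138, a ubiquitin ligase, fell by 1.12, SKP1 by 0.83, the cullin gene CUL2 by 0.59 and SPOP by 0.55, and the F-box gene FBXL12 rose by 0.55. SCML2, a relative of SCML1, fell by 1.11, the acetyltransferase gene KAT2B by 0.97, CBX6 by 0.74, PCGF5 by 0.56 and the deacetylase gene HDAC4 by 0.47. SCML2 stood at 3.55 in T98G with the mimic, below the filter level of 4.28, so its size is uncertain there. The DNA methyltransferase gene DNMT3B rose by 0.67. The genes given here by name passed limma's adjusted threshold over all genes.

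CPEB4, which binds messenger RNA, fell by 0.55 and RC3H2 by 0.48. MICB at -0.82 ± 0.04 and MICA at -0.63, which encode some of the ligands of the immune receptor NKG2D, fell. DDIAS fell by 0.92 and RMI1, a partner of the BLM helicase, by 0.63, and RIF1, which acts in the choice of double-strand break repair, rose by 0.49. SOAT1, which esterifies cholesterol, fell by 1.03 and INSIG2, which restrains sterol synthesis, by 0.59. The Hedgehog receptor PTCH1 fell by 0.49 and LIFR by 0.67, while RBPJ, the DNA-binding partner of Notch, rose by 0.67 and the phosphatase PTPN1 by 0.68.

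The test with 1 line left out in this paragraph was chosen after its result was seen. Lower genes outnumbered higher ones 2.48 to 1 among the calls. With each line's loess trend removed the ratio was 2.54, which argues against an intensity trend. Among genes changed by at least 0.5 in both remaining lines, lower genes outnumbered higher ones 1.84 to 1 without T98G, 3.06 without A172 and 2.65 without U87MG, which argues against 1 line alone carrying the excess. It was not alike in the lines: A172 by itself had 270 genes higher and 238 lower by at least 0.5, T98G 201 and 310, and U87MG 190 and 254, and without A172 limma called 10 genes higher and 51 lower. An excess of lower genes would be consistent with direct silencing by the microRNA, as a hypothesis; the seed match comparison that could bear on it was not run. A batch that followed the groups stays open as well. The real split of the arrays called 153 genes, and the other 3 splits that part every pair of arrays of a line called 0 each with limma (399 to 457 at an unadjusted p under 0.05, against 1634). Each of these 3 splits reverses 1 line, which puts much of an effect shared by the lines into the error and lowers their calls. The remaining 6 of the 10 splits part 1 pair, so that with the line in the model the group effect rests on that pair; they come in duplicates, and the highest called 3. Only 1 of the 10, the real one, called as many, and with so few splits the share cannot fall under 0.05.

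The small shifts of the called lists were weighed in the same way. After loess removal 7 of the 8 called lists still passed, and the ribosomal list did not (adjusted p = 0.172), which argues against an intensity trend for the 7. Among the 3 other splits that part every pair of arrays of a line, the highest called 5 lists. Each of these splits reverses 1 line. It therefore keeps part of a shared effect of the mimic and all of a response of 1 line alone. Calls from these splits do not by themselves show drift of whole lists between cultures or arrays, unrelated to the mimic. Drift of that kind may still account for part of the calls and cannot be told apart from an effect of the mimic with so few splits. Only 1 of the 10, the real split, called as many as 8 lists; the splits that part 1 pair, which rest on that pair alone, called at most 5 as well, and again the share cannot fall under 0.05.

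Of 1303 tested probe sets with several symbols and 5034 with none, 0 passed limma's adjusted threshold, with 54 and 351 at an unadjusted p under 0.05. They were fitted apart from the genes, with 4.42 degrees of freedom in the moderated test against 6.56. The smallest p among them was 1.17e-05 (adjusted p = 0.074), for a probe set with several symbols, left unnamed for that reason, that differed by -1.62 (-1.63 in A172, -1.58 in T98G and -1.65 in U87MG), a larger difference than that of PPP2R5A.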
